A study of Mus musculus with 31 samples.

How the data were processed

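Chromatin immunoprecipitation followed by sequencing was done on lung adenocarcinomas of mice of mixed 129/B6 background, aged 4 to 7 months per the labels. Single-end reads of 40 to 50 nucleotides were made, per the labels' protocols. The submitters' processing notes name Bowtie, MACS 1.4.2, SICER 1.1 and build mm9, without a role for each. The names of the peak lists carry a p of 1e-06, and those of the island lists a window of 200 bp, a gap of 200 bp (H3K27ac, H3K4me3) or 600 bp (H3K4me1, H3K27me3) and an FDR of 0.01. These names and the track headers mark the lists as merged. Each deposited peak carries the score that the authors' peak caller gave it, at least 60, and a summit. Each deposited island carries a read count from the authors' island caller, not scaled for depth. Score and count were used to rank or filter within a list, and the count also to give read density, total reads in islands and the share of island reads on chromosomes X and Y. Single values were not compared between lists, since their scale differs.

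Samples were grouped by target and tumor type from the titles and the Nkx2-1 status. The 22 files of 11 groups were compared byte by byte, and the 2 files of each group were identical, so each group was used as 1 list. No replicate spread exists and no p-value was computed. The 9 input samples were not used here. A peak or island counted as shared when it overlapped the other list by at least 1 bp. Lost means present in positive tumors only, gained present in deleted tumors only, and kept shared, counted in the positive list. A mark was present at a peak when an island covered at least 1 bp of it. Shares have 95% Wilson intervals, and differences have 95% intervals from a jackknife over 20 chromosomes (19 autosomes and X), with the number of chromosomes that show the direction. Background shares come from 100 random placements of the same intervals on their chromosomes, with a fixed seed. Computation used Python 3.11.15 with numpy 2.4.6, and figures matplotlib 3.10.9.

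On simulated Foxa1/2 lists of 22831 peaks with a set overlap of 41.8%, the overlap rules gave 42.1%, 41.9% and 41.9% (1 bp, 50% and summit rule). A set change of -20.6 points came back as -20.6, as it must, since the simulated marks were copies of the peaks themselves. The chance share of 2.49% calculated from the widths came back as 2.47% from placement, and jackknife intervals held the true share in 92.5% of 200 draws, against a nominal 95%. Those draws marked peaks independently and for a single share, so clustering along chromosomes and differences were not tested.

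The comparisons, the overlap rules and the alternatives were fixed before the data were examined. The alternatives were an overlap of 50% of the shorter interval, summits within 200 bp and the upper part of each list. Further ones were equal numbers of peaks, islands that cover the summit, and autosomes only. Equal numbers cut the Nkx2-1 list and both Foxa1/2 lists to as many peaks as the upper 50% of the shorter Foxa1/2 list holds. Placement under islands, its restriction for gained peaks to places off positive-tumor Foxa1/2 peaks, and lists cut to equal covered length were added after the data had been seen, and the cut by count after the result of the cut by density. The cut to equal covered length was made on the longer list, which was the positive one for each mark. An alternative was counted as within the main interval by the Wilson interval for shares and the jackknife interval for differences. The rule for named regions was, for each comparison of lists, the 3 widest peaks or islands present in 1 tumor type only, per direction, given by 1-based mm9 coordinates. This is the form of the rule for the case that no gene annotation of the build is at hand. The annotation at hand is of another build, so no region was assigned to a gene, and the planned gene lists and motif searches were not analysed here.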

Results

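The study profiled mouse lung adenocarcinomas that either retained Nkx2-1 (positive tumors) or had the gene deleted (deleted tumors). Nkx2-1 is a homeodomain transcription factor of the lung lineage. Foxa1 and Foxa2 are forkhead transcription factors of endoderm-derived epithelia, and 1 antibody against both was used. Nkx2-1 binding was measured in positive tumors. Foxa1/2 binding and 4 histone marks were measured in both tumor types: H3K27ac (active promoters and enhancers), H3K4me1 (enhancers), H3K4me3 (promoters) and H3K27me3 (Polycomb-silenced chromatin). Of 31 samples, 9 were inputs, and the other 22 formed 11 groups of 2 libraries. Both files of each group were identical, so each group gave 1 pooled list and no difference below has a replicate check. Tumor type and mouse sex coincided for Foxa1/2, with 2 male mice for positive tumors and 2 female mice for deleted tumors. Both Nkx2-1 libraries were also male, so the Nkx2-1 list matches the positive-tumor Foxa1/2 list in sex and not the deleted-tumor list. The histone groups each held 1 male and 1 female. Per the labels, 1 input served both an Nkx2-1 library and the male histone libraries of positive tumors, so the Nkx2-1 peaks share a control with positive-tumor marks and not with deleted-tumor marks.

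The Nkx2-1 list held 29782 peaks, with a median width of 927 bp. The Foxa1/2 list held 23039 peaks in positive tumors and 14526 in deleted tumors. H3K27ac islands numbered 73539 in positive and 61981 in deleted tumors, and H3K4me1 islands 79623 and 66879. H3K4me3 islands numbered 41584 and 30992, and H3K27me3 islands 53052 and 51840. Reads inside islands, the only depth the lists give, came to 45.7 and 31.2 M for H3K27ac, 35.8 and 29.8 M for H3K4me1, 28.9 and 19.6 M for H3K4me3, and 18.5 and 19.8 M for H3K27me3. The total depth of the libraries is not given in the sources used here. Shares below carry 95% Wilson intervals over peaks or islands, which cover counting error only. Differences between shares carry 95% intervals from leaving out each of 20 chromosomes in turn, which cover variation along the genome and not between mice.

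Nkx2-1 and Foxa1/2 occupied many of the same places in positive tumors. Of the Nkx2-1 peaks, 14180 (47.6%, interval 47.0 to 48.2) overlapped a Foxa1/2 peak, and 61.4% (60.8 to 62.0) of the Foxa1/2 peaks overlapped an Nkx2-1 peak. Random placement of the Nkx2-1 peaks on the same chromosomes gave a mean of 1.93% and at most 2.15% over 100 draws. Placement under H3K4me1 or H3K27ac islands of positive tumors, a stricter background chosen after seeing the data, gave a mean of 11.2%, so the observed share was 4.25 times that background. The summits of overlapping peaks lay a median of 70 bp apart. The shared portion rose with the Nkx2-1 peak score, from 25.3% (23.8 to 26.97) in the lowest of 10 score groups to 85.0% (83.6 to 86.2) in the highest.

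The Foxa1/2 peak lists differed between the tumor types. Of the positive-tumor peaks, 13376 (58.1%, interval 57.4 to 58.7) had no peak at the same place in deleted tumors and are called lost. The other 9663 were kept. Of the deleted-tumor peaks, 4794 (33.0%, interval 32.2 to 33.8) had no counterpart in positive tumors and are called gained. Random placement of the positive-tumor peaks gave 1.16% shared, against 41.9% observed, and kept peaks had summits a median of 22 bp apart. The order of the lost and gained shares follows in part from the lengths of the lists and does not show which direction prevailed. With equal numbers of top-scoring peaks, which makes both shares nearly equal by construction, 51.5% were lost and 51.2% were gained.

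High-scoring peaks were kept more often than low-scoring peaks. The kept share of positive-tumor Foxa1/2 peaks rose from 20.8% (19.1 to 22.5) in the lowest of 10 score groups to 76.9% (75.1 to 78.6) in the highest. Lost peaks had a median score of 137 and kept peaks of 314. In the deleted-tumor list, gained peaks made up 57.9% (55.3 to 60.5) of the lowest score group and 5.30% (4.26 to 6.57) of the highest. Whether a lost or gained peak lay just below the calling threshold in the other list was not tested.

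The widest lost Foxa1/2 peaks (build mm9) lay on chromosome 1 at 90172295 to 90177389 (5095 bp), chromosome 10 at 87811260 to 87816087 (4828 bp) and chromosome 11 at 111285602 to 111289685 (4084 bp). The peak on chromosome 10 overlapped 1 Nkx2-1 peak and that on chromosome 11 overlapped 2 Nkx2-1 peaks. H3K27ac islands covered 100% of both in both tumor types. H3K4me3 covered 93.0% of the peak on chromosome 11 in positive tumors and 49.0% in deleted tumors. The peak on chromosome 1 had no Nkx2-1 peak, and H3K27me3 covered 66.5% of it in deleted and 0% in positive tumors. It lay in a stretch of unusually dense islands, under an H3K4me1 island denser than 99.95% of its list in positive and 99.96% in deleted tumors. The widest gained peaks lay on chromosome 12 at 78298119 to 78300323 (2205 bp), chromosome 2 at 58555657 to 58557807 (2151 bp) and chromosome 15 at 54351729 to 54353829 (2101 bp). None of these 3 overlapped an Nkx2-1 peak. H3K27ac covered 100% of the peak on chromosome 12 in both tumor types. Its covered length at the peak on chromosome 2 went from 83.7% in positive to 100% in deleted tumors, and at the peak on chromosome 15 from 57.1% to 81.0%.

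The comparison of peak classes with Nkx2-1 binding asks where Foxa1/2 lies relative to Nkx2-1 when Nkx2-1 is removed. Nkx2-1 peaks of positive tumors overlapped 66.3% (65.5 to 67.1) of lost Foxa1/2 peaks, 54.7% (53.7 to 55.7) of kept peaks and 7.91% (7.18 to 8.70) of gained peaks. The share was 58.4 percentage points higher in lost than in gained peaks (57.0 to 59.7) and 11.6 points higher in lost than in kept peaks (10.2 to 13.1). Both differences had this direction on 20 of 20 chromosomes. With equal numbers of top-scoring peaks in both Foxa1/2 lists and the Nkx2-1 list, they were 49.4 and 21.1 points. Lost peaks then also include those whose counterpart in deleted tumors fell below the cut. Random placement gave 2.35% for lost, 2.58% for kept and 2.23% for gained peaks. Under H3K4me1 or H3K27ac islands of positive tumors, the stricter background, placement gave 14.1% for lost and 15.2% for kept peaks. Gained peaks by definition avoid every positive-tumor Foxa1/2 peak. They can therefore overlap the 14180 Nkx2-1 peaks shared with Foxa1/2 only outside those Foxa1/2 peaks. Part of the difference between gained and other peaks thus follows from the classes, and the size of that part was not measured. Placement of gained peaks under H3K4me1 or H3K27ac islands of deleted tumors gave 14.4%, and 8.41% (range 7.25 to 9.72) when counted only off positive-tumor Foxa1/2 peaks, a step added after seeing the data. The observed 7.91% lay within that range.

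**Figure D1:**
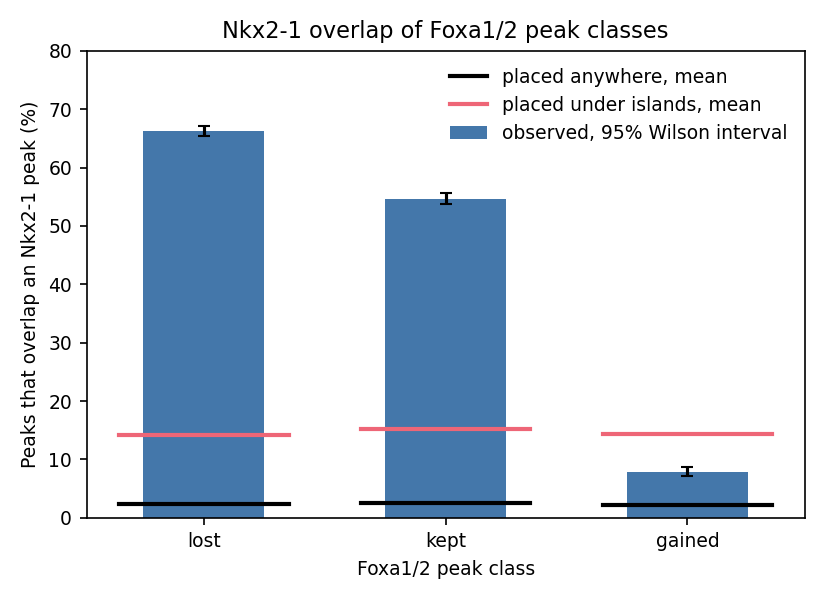
Bars give the share of lost, kept and gained Foxa1/2 peaks (percent) that overlap an Nkx2-1 peak of positive tumors, with 95% Wilson intervals; lines mark the means of 100 random placements on the same chromosomes (black) or under H3K4me1 or H3K27ac islands (red). The share is 66.3% for lost, 54.7% for kept and 7.91% for gained peaks.

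The difference between lost and kept Foxa1/2 peaks was present at every level of the score. In the lowest score group of the positive list, 43.1% of lost and 19.6% of kept peaks overlapped Nkx2-1, a difference of 23.6 points (20.0 to 27.1). In the highest group the shares were 97.9% and 90.0%, a difference of 7.96 points (5.85 to 10.1). In the deleted-tumor list, gained peaks overlapped Nkx2-1 in 9.002% of cases in the lowest group and 6.49% in the highest, against 57.1% and 60.9% of kept peaks, a contrast that the classes set in part.

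**Figure D2:**
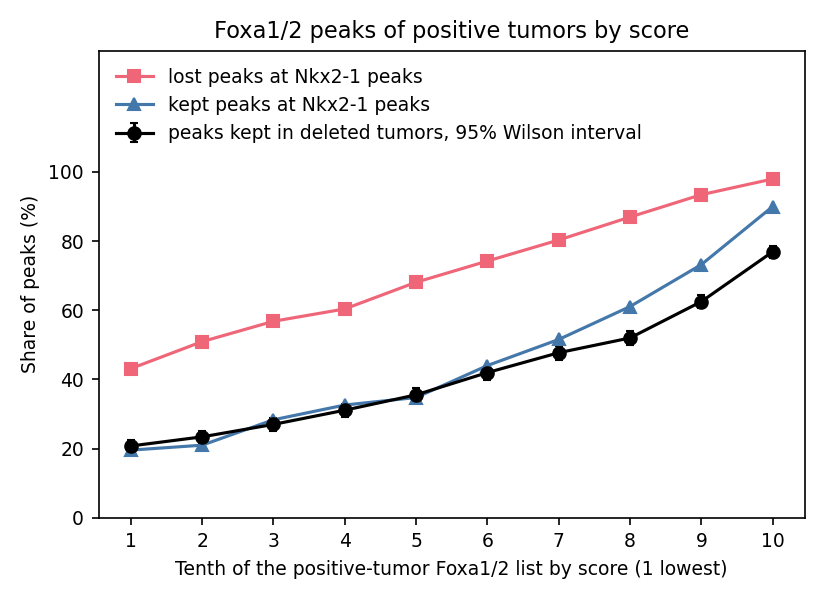
Foxa1/2 peaks of positive tumors are divided into 10 groups by peak score (x axis, 1 lowest), and the y axis gives shares of peaks in percent: peaks kept in deleted tumors (black, 95% Wilson intervals), lost peaks at Nkx2-1 peaks (red) and kept peaks at Nkx2-1 peaks (blue). The kept share rises from 20.8% to 76.9%, and the red points lie above the blue points in each of the 10 groups.

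H3K27ac changed in opposite directions at lost and gained Foxa1/2 peaks. It covered 88.01% (87.4 to 88.5) of lost peaks in positive tumors and 67.6% (66.8 to 68.3) in deleted tumors, so the share fell by 20.5 points (interval -21.8 to -19.1; 20 of 20 chromosomes). At gained peaks it went from 67.1% (65.7 to 68.4) to 81.7% (80.6 to 82.8), a rise of 14.6 points (13.01 to 16.2; 20 of 20 chromosomes). At kept peaks the values were 93.0% and 92.0%. Random placement gave 14.5% for lost peaks in positive tumors. With the positive list cut to the covered length of the deleted list, a step added after seeing the data, the fall at lost peaks shrank to -7.60 or -5.53 points, depending on how islands were ranked. The rise at gained peaks then grew to 30.04 or 32.4 points, and kept peaks rose by 7.87 or 9.99 points. The cut drops islands from the positive list only, so each change shifts toward deleted tumors by construction.

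H3K4me1, the enhancer mark, moved in the same directions as H3K27ac at lost and gained peaks. Its share at lost Foxa1/2 peaks fell by 9.19 points (-10.2 to -8.13), from 97.2% to 88.1%. At gained peaks it rose by 14.1 points (12.8 to 15.4), from 77.3% to 91.4%, and at kept peaks it was 97.4% in both tumor types. The change at kept peaks was above 0 with equal covered length by count, at 3.43 points (3.02 to 3.83), or by density, at 0.849 (0.646 to 1.05), and with islands that cover the summit, at 0.735 (0.383 to 1.09). The fall at lost peaks was -19.2 points with the upper 50% of each island list by count, and -8.21 or -5.0015 points with equal covered length by density or count. The rise at gained peaks was 24.1 points with equal covered length by count. Of the 2814 lost peaks with H3K27ac in positive tumors only, 76.9% (75.3 to 78.4) lay under an H3K4me1 island in deleted tumors, and 3.62% (3.00 to 4.38) lay under an H3K27me3 island there. Of the 813 gained peaks with H3K27ac in deleted tumors only, 46.2% (42.8 to 49.7) had H3K4me1 in positive tumors.

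H3K4me3 islands covered fewer peaks of every class in deleted tumors. The share went from 55.7% to 26.7% at lost, from 66.7% to 49.6% at kept and from 30.3% to 26.1% at gained Foxa1/2 peaks. The fall at lost peaks was -13.8 points with the upper 50% of each island list, against -29.0 with all islands. The directions turned with the positive list cut to equal covered length: ranked by read density, the differences became 7.78, 21.8 and 12.3 points in favor of deleted tumors. Since only the positive list loses islands in this cut, a shift toward deleted tumors follows by construction. H3K27me3 covered few Foxa1/2 peaks, at 2.72% (2.46 to 3.01) of lost and 8.41% (7.65 to 9.23) of gained peaks in positive tumors, against 21.1% and 20.9% under random placement. It rose by 1.08 points at lost peaks (0.493 to 1.66) and by 0.642 points at kept peaks (0.213 to 1.07). With islands that cover the summit, the value at kept peaks was 0.352 (-0.0406 to 0.744). Its change at gained peaks, 0.396 points, had an interval that reached 0 (-0.442 to 1.24). That change was 0.688 points (0.0827 to 1.29) with the upper 50% of each island list by count and 0.814 (0.0422 to 1.58) with equal covered length by density, so whether it differs from 0 depends on the setting.

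**Figure D3:**
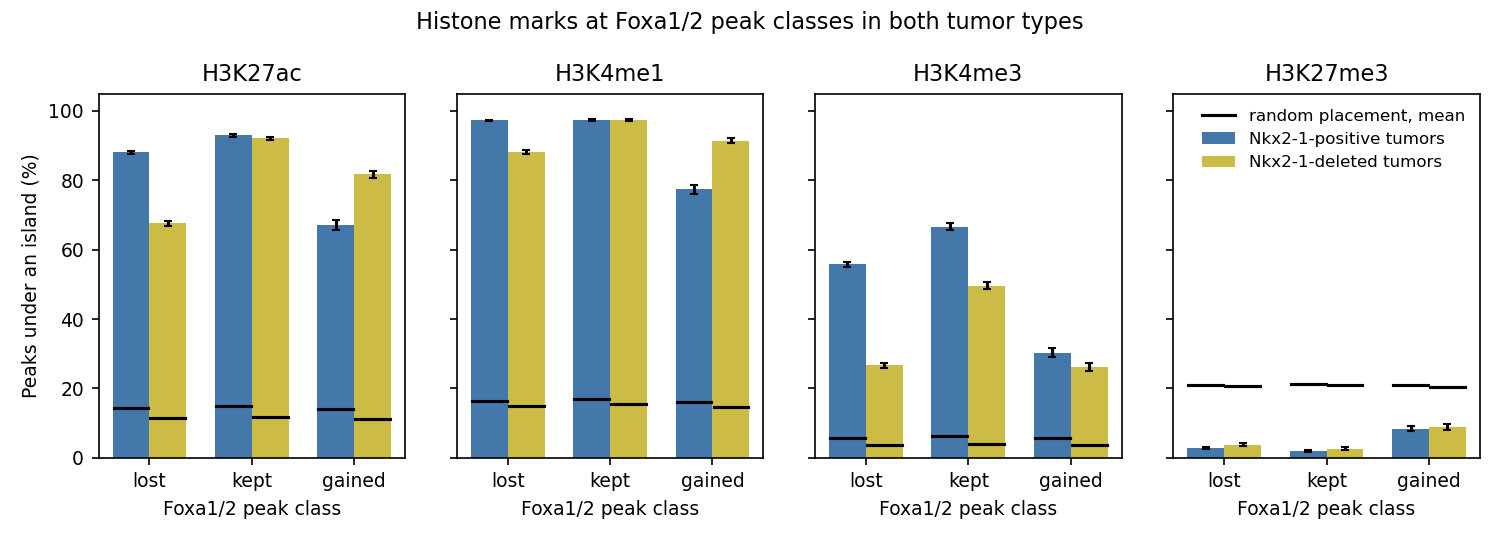
Each panel shows 1 histone mark; bars give the share of lost, kept and gained Foxa1/2 peaks (percent) under an island in positive (blue) and deleted (yellow) tumors with 95% Wilson intervals, and black lines give the mean of 100 random placements. H3K27ac falls from 88.01% to 67.6% at lost peaks and rises from 67.1% to 81.7% at gained peaks.

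At Nkx2-1 peaks the active marks were less frequent in deleted tumors. H3K27ac covered 93.2% (92.9 to 93.5) of the peaks in positive tumors and 79.9% (79.5 to 80.4) in deleted tumors. The share fell by 13.7 points at Nkx2-1 peaks shared with Foxa1/2 (-14.8 to -12.7) and fell by 12.9 points at those not shared (-14.0 to -11.7). With the upper 50% of each island list by count these values were -18.7 (-20.2 to -17.3) and -12.3 (-13.3 to -11.2). H3K4me1 went from 98.4% to 92.2% and H3K4me3 from 68.1% to 45.1%. At Nkx2-1 peaks shared with Foxa1/2, H3K4me1 fell by 4.48 points and H3K4me3 fell by 30.5 points; with the upper 50% of each island list by count the values were -14.1 and -18.3. At those not shared, H3K4me1 changed by -7.79 points, or -3.70 with equal covered length by count. H3K4me3 there changed by -16.1 points, or -9.18 with the upper 50% of each list. H3K27me3 rose from 2.01% (1.86 to 2.18) to 3.44% (3.24 to 3.65), with 19 of 20 chromosomes in that direction. With equal covered length the H3K27ac fall at shared peaks was -6.09 or -4.49 points, while at peaks not shared it was -2.47 or turned to 0.865 points, and H3K4me3 turned at both. The cut again drops islands from the positive list only.

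In the lists as deposited, islands of the active marks were lost more often than gained. Of positive-tumor H3K27ac islands, 23730 (32.3%, interval 31.9 to 32.6) were lost, and 6708 (10.8%, 10.6 to 11.1) of deleted-tumor islands were gained. For H3K4me1, 18356 (23.1%) were lost and 5609 (8.39%) gained, and for H3K4me3, 13103 (31.5%) were lost and 1004 (3.24%) gained. The positive lists also covered more bases: 291.8 against 227.1 Mb for H3K27ac, 329.4 against 300.4 Mb for H3K4me1 and 104.3 against 64.0 Mb for H3K4me3. Mean read density inside islands was 157 and 137 reads per kb for H3K27ac, 109 and 99.1 for H3K4me1, and 277 and 305 for H3K4me3. The Jaccard index over bases was 0.613, 0.700 and 0.582. Cutting to equal covered length drops islands from the positive list only, so fewer lost and more gained islands follow in part by construction. After the cut the gained share exceeded the lost share for H3K27ac (31.1% against 11.4%, ranked by read density) and H3K4me3 (40.7% against 0.250%). As deposited, only 3.24% of deleted-tumor H3K4me3 islands overlapped no positive-tumor island. For H3K4me1 the order turned only when islands were ranked by count, with 21.6% gained and 11.0% lost. Neither the order as deposited nor the order after the cut shows which direction prevailed.

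Lost and gained H3K27ac islands held different factors, in part by definition. Nkx2-1 was measured in positive tumors only, where 93.2% of its peaks lay under H3K27ac, and gained islands overlap no positive-tumor island. Nkx2-1 peaks lay in 13.9% (13.4 to 14.3) of lost and 1.65% (1.38 to 1.99) of gained H3K27ac islands, and in 33.0% of kept islands, which were wider (median 3200 bp against 1400 bp for both other classes). Gained Foxa1/2 peaks lay in 9.82% (9.13 to 10.6) of gained and 0.329% (0.264 to 0.410) of lost H3K27ac islands. For H3K4me1, gained Foxa1/2 peaks lay in 9.38% (8.64 to 10.2) of gained and 0.180% (0.128 to 0.252) of lost islands. Lost islands likewise overlap no deleted-tumor island, under which most gained Foxa1/2 peaks lay.

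The widest lost H3K27ac islands lay on chromosome 18 at 68500201 to 68517400 (17200 bp), chromosome 9 at 23493201 to 23509800 (16600 bp) and chromosome 6 at 53864201 to 53879800 (15600 bp). They held 1, 2 and 3 Nkx2-1 peaks and 1, 3 and 3 positive-tumor Foxa1/2 peaks, with 0 Foxa1/2 peaks in deleted tumors. H3K4me1 covered 79.1% of the region on chromosome 18 in positive and 38.4% in deleted tumors, and the region on chromosome 9 went from 77.1% to 28.9%. The widest gained H3K27ac islands lay on chromosome 5 at 73748201 to 73767800 (19600 bp), chromosome 18 at 25785801 to 25803400 (17600 bp) and chromosome 3 at 100332601 to 100346000 (13400 bp). None held an Nkx2-1 peak or a positive-tumor Foxa1/2 peak, and those on chromosomes 5 and 3 each held 1 Foxa1/2 peak of deleted tumors. H3K4me1 cover went from 16.3% to 67.3% on chromosome 5, from 18.2% to 95.5% on chromosome 18 and from 13.4% to 74.6% on chromosome 3.

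The widest gained H3K4me1 islands lay on chromosome 17 at 25886201 to 25896000, chromosome 4 at 131706201 to 131714600 and chromosome 1 at 140534401 to 140542200. All 3 were covered by H3K27ac over 100% of their length in deleted tumors and 0% in positive tumors, and held 1, 2 and 1 deleted-tumor Foxa1/2 peaks. H3K27me3 cover also rose, from 63.3% to 98.0% on chromosome 17 and from 0% to 26.2% on chromosome 4, and was 0% in both tumor types on chromosome 1. The third widest gained H3K4me3 island, on chromosome 17 at 25888201 to 25891800, lay inside the first of these. The other wide gained H3K4me3 islands lay on chromosome 7 at 31857401 to 31862200, with 1 deleted-tumor Foxa1/2 peak, and chromosome 12 at 103592201 to 103596000. The widest lost H3K4me3 islands, on chromosome 8 at 12798001 to 12808000, chromosome 18 at 55085001 to 55094800 and chromosome 4 at 118065601 to 118075200, stayed under H3K27ac and H3K4me1 over 100% of their length in both tumor types. They held 4, 3 and 3 Nkx2-1 peaks.

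The widest lost H3K4me1 islands lay on chromosome 1 at 90148601 to 90167000, chromosome 9 at 72399601 to 72415400 and chromosome 11 at 68274801 to 68290400, and held 0 Nkx2-1 peaks. The widest gained H3K27me3 island overlapped the first of these, on chromosome 1 at 90122001 to 90158600 (36600 bp). Its density of 107.5 reads per kb exceeded that of 99.96% of the islands in its list, and the lost H3K4me1 island, at 183 reads per kb, exceeded 98.6% of its list. The widest lost Foxa1/2 peak lay in the same stretch, so copy number or read mapping, which were not examined, leave all 3 of these regions in doubt. Other wide gained H3K27me3 islands lay on chromosome 15 at 100620801 to 100639200 and chromosome 16 at 34535401 to 34553200. The widest lost H3K27me3 islands lay on chromosome X at 80054601 to 80077400 and at 89930801 to 89952200, and on chromosome 1 at 145307401 to 145329400.

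H3K27me3 islands were lost and gained in like numbers, with chromosome X apart. Genome-wide 10493 islands (19.8%, 19.4 to 20.1) were lost and 9253 (17.8%, 17.5 to 18.2) gained, and the order turned on autosomes, with 17.2% lost and 18.3% gained. The lists covered 481.3 and 462.6 Mb at 38.5 and 42.8 reads per kb, and the Jaccard index was 0.662. On chromosome X the covered length was 27.7 Mb in positive and 14.3 Mb in deleted tumors, a ratio of 0.517, while the autosomes together gave 0.988. Against the autosomes together, H3K4me1 gave 0.783 on chromosome X and 0.9145, H3K27ac 0.7355 and 0.779, and H3K4me3 0.698 and 0.612. The H3K27ac value lay within the spread of single autosomes, from 0.7265 on chromosome 18 to 0.841 on chromosome 7. The H3K4me1 value lay below the lowest autosome (0.8715, chromosome 13), and the H3K4me3 value above the highest (0.664, chromosome 7). Chromosome X took 5.06% of H3K27me3 island reads in positive and 2.42% in deleted tumors. Nkx2-1 peaks lay in 2.41% (2.12 to 2.74) of gained and 0.362% (0.264 to 0.497) of lost H3K27me3 islands; few Nkx2-1 peaks lay under positive-tumor H3K27me3, so this contrast too is set in part by the classes.

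**Figure D4:**
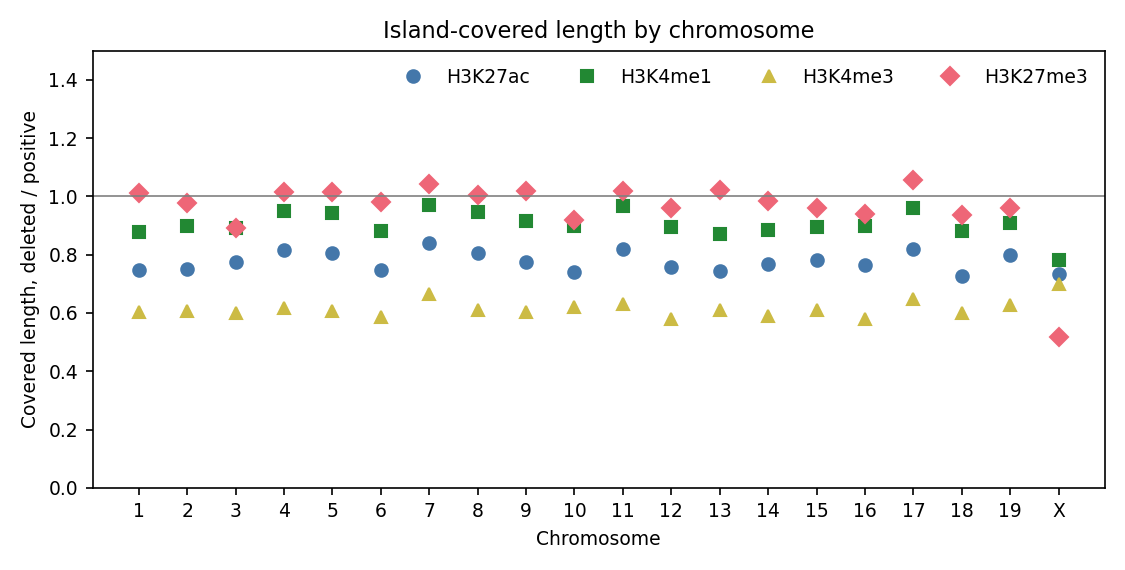
Each point is the island-covered length of 1 mark on 1 chromosome (x axis) in deleted tumors divided by that in positive tumors (y axis, no unit); the grey line marks equal length. H3K27me3 lies between 0.890 and 1.06 on the autosomes and at 0.517 on chromosome X.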

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

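Both forms of placement under islands and both cuts to equal covered length were chosen after seeing the data, and the cut by count after seeing the cut by density; the other alternatives were planned. No paired analysis was possible because the 2 files of each group are identical pooled lists, so no replicate could be left out or matched. The planned gene list and motif results were not run, since the annotation used here is of another build and no sequence was used. Of 156 alternatives for 37 values, 66 stayed within the interval of the main value, 75 moved outside it and 15 turned direction. Of 100 alternatives for differences between shares, 87 kept the sign. The cause of the changes below was not tested, except that a cut list holds fewer bases by construction.

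Requiring 50% of the shorter interval gave 46.2% of Nkx2-1 peaks shared with Foxa1/2, 32.8% of H3K27ac islands lost and 11.3% gained, 23.4% and 8.60% for H3K4me1, and 22.4% and 20.9% for H3K27me3. With summits within 200 bp, 37.5% of Nkx2-1 peaks were shared, and 60.8% of Foxa1/2 peaks were lost and 37.8% gained. The Nkx2-1 overlap of lost peaks then exceeded that of gained peaks by 49.4 and of kept peaks by 15.1 points. The upper 50% of each peak list by score gave 42.2% of Nkx2-1 peaks shared. Equal numbers of peaks, which fix both shares near each other by construction, gave 51.5% lost and 51.2% gained. With the Nkx2-1 list cut to the same number, the Nkx2-1 overlap differences were 49.4 (lost minus gained) and 21.1 points (lost minus kept).

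With the upper 50% of each island list by count, H3K27ac changed by -23.5 points at lost and -1.60 at kept Foxa1/2 peaks, and by -18.7 at shared and -12.3 at other Nkx2-1 peaks. At lost Foxa1/2 peaks H3K4me1 changed by -19.2 and H3K4me3 by -13.8 points. At shared Nkx2-1 peaks H3K4me1 changed by -14.1 and H3K4me3 by -18.3, and at others H3K4me3 by -9.18. Islands lost and gained were then 29.0% and 11.1% for H3K27ac. H3K4me1 gains were 9.48%, H3K4me3 losses and gains 26.8% and 0.355%, and H3K27me3 gains 20.3%. On autosomes, H3K27me3 losses were 17.2% and gains 18.3%.

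With equal covered length, values are for islands ranked by density, then by count. The cut drops islands from the positive list only, so differences shift toward deleted tumors by construction. H3K27ac changed by -7.60 and -5.53 points at lost, 7.87 and 9.99 at kept, and 30.04 and 32.4 at gained Foxa1/2 peaks. At Nkx2-1 peaks it changed by -6.09 and -4.49 (shared with Foxa1/2) and -2.47 and 0.865 points (not shared). H3K4me1 changed by -8.21 and -5.0015 at lost, and 17.9 and 24.1 at gained Foxa1/2 peaks. H3K4me3 turned to 7.78 and 6.71 at lost, 21.8 and 21.3 at kept, and 12.3 and 12.3 at gained Foxa1/2 peaks. At Nkx2-1 peaks it turned to 16.1 and 14.5 (shared), and 6.86 and 7.49 points (not shared). H3K27ac islands were 11.4% and 7.11% lost, and 31.1% and 36.8% gained. H3K4me1 islands were 18.1% and 11.0% lost, and 14.7% and 21.6% gained. H3K4me3 islands were 0.250% and 0.447% lost, and 40.7% and 47.3% gained. H3K27me3 islands were 17.5% and 17.1% lost, and 20.3% and 22.8% gained. Against placement under islands, the Nkx2-1 peaks shared with Foxa1/2 were 4.25 times the background, and the gained Foxa1/2 peaks at Nkx2-1 peaks 0.549 times. Gained peaks avoid positive-tumor Foxa1/2 peaks by definition, which limits their overlap with the Nkx2-1 peaks shared with Foxa1/2. Against placements that avoid positive-tumor Foxa1/2 peaks too, they were 0.941 times the background (0.854 to 1.04), which does not part them from it.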

Other observations

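Islands that carried H3K4me3 in both tumor types lay under H3K27me3 in deleted tumors only more often than in positive tumors only. Among 28481 kept H3K4me3 islands, 4813 (16.9%, interval 16.5 to 17.3) lay under H3K27me3 in both tumor types, 1128 (3.96%, 3.74 to 4.19) in deleted tumors only and 220 (0.772%, 0.677 to 0.881) in positive tumors only. On autosomes the counts were 1099 and 149, and no other alternative was run. The deleted H3K27me3 list held more island reads (19.8 against 18.5 M) at a higher density (42.8 against 38.5 reads per kb), which was not matched here. Nkx2-1 peaks lay in 23.2% (20.9 to 25.8) of the islands with H3K27me3 in deleted tumors only, in 18.2% (13.6 to 23.8) of those with it in positive tumors only and in 48.5% (47.8 to 49.1) of those with no H3K27me3. Of the islands with H3K27me3 in deleted tumors only, 82.0% had H3K27ac in positive and 80.9% in deleted tumors.

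Lost or gained Foxa1/2 peaks lay several to a window of 500 kb at some places. The window with the largest excess of lost peaks, on chromosome 14 from 79500001 to 80000000, held 23 lost, 6 kept and 0 gained peaks with 22 Nkx2-1 peaks, and its H3K27ac cover was 266.8 kb in positive and 156.6 kb in deleted tumors. The window with the largest excess of gained peaks, on chromosome 17 from 47500001 to 48000000, held 1 lost, 5 kept and 9 gained peaks with 19 Nkx2-1 peaks. Its H3K27ac cover was 184.2 kb in positive and 173.6 kb in deleted tumors. The deleted H3K27ac list covered 0.778 times the length of the positive list genome-wide and 0.818 times on chromosome 17. That drop was larger than in the chromosome 17 window and smaller than in the chromosome 14 window. These windows were chosen after their values were seen, out of 3565 with a Foxa1/2 peak, and no chance level was computed.

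The tests on peak scores, on joint density and count, and on chromosome X were chosen after the result was seen, as was the cut by count. Lost Foxa1/2 peaks lay at Nkx2-1 peaks more often than kept ones. Weak peaks near the calling threshold were weighed through the scores of the positive list. These scores alone give -11.2 points (-11.9 to -10.5) for lost minus kept, against 11.6 observed. The negative sign was set beforehand, since lost peaks score lower and Nkx2-1 overlap rises with score. Lower scores in the positive list therefore do not give the difference. Whether lost peaks lay just below the threshold of the deleted list was not tested. Sites active only in positive tumors would remove it among peaks with H3K27ac in both tumor types, where it was 12.6 points (11.1 to 14.1). An island in both lists does not show equal activity at the peak, so sites with weaker H3K27ac in deleted tumors were not tested. The loss of Nkx2-1 and mouse sex coincide for Foxa1/2, and both remain open as untested.

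H3K27ac fell at lost Foxa1/2 peaks. Lower depth or yield of the deleted list was tested by matching lost and kept peaks on density of the positive island. Kept peaks then retained H3K27ac more often by 17.5 points (16.7 to 18.4), and by 19.4 points (18.1 to 20.8) with read count matched too. Matching used whole islands and not the mark at the peak, and kept peaks had higher Foxa1/2 scores (median 314 against 137). The test therefore cannot exclude lower depth or yield. The difference between kept and lost peaks lay mostly in the less dense islands. It went from 51.5 points in the least dense of 10 groups to 0.583 in the densest, where 99.4% of lost and 100% of kept peaks retained the mark. The longer positive list was tested by the cut to equal covered length. The fall was then -7.60 points by density (-8.59 to -6.61), past the bound of 5 points set beforehand. By count it was -5.53 (-6.40 to -4.67), below 0 but not past that bound with its whole interval. Relative to kept peaks, the change was -19.5 points as reported and -15.5 under both cuts. A fall relative to kept peaks thus remained at equal covered length. The cut drops whole islands and does not imitate lower depth, so it cannot decide whether the longer list accounts for the fall. H3K27ac may follow Foxa1/2 binding or precede it, and neither order, nor the share of tumor cells per sample, was tested.

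H3K27me3 covered less of chromosome X in deleted tumors, at a ratio of 0.517. Less H3K27me3 on all chromosomes would give a like ratio on autosomes, whose lowest value was 0.890, and a few large regions would spare most of the chromosome, but 94.3% (88.6 to 97.2) of 122 windows of 1 Mb had less. The silenced X of female mice carries much H3K27me3, so fewer reads of the female mouse in the deleted pool could lower it. Chromosome Y took a higher share of island reads in deleted tumors for 1 of the other 3 marks, H3K27ac (13.6 and 23.4 per M reads), and a lower share for H3K4me1 (18.0 and 10.8) and H3K4me3 (95.04 and 79.0). These shares rest on only 3 or 4 chromosome Y islands per list. The marks were also pooled separately, so the pool and a loss of the silenced X in tumors cannot be told apart.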
